A study of Mus musculus with 4 samples.

How the data were processed

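Gene expression was measured by RNA-seq in ASZ001 cells, a mouse BCC line, after doxycycline treatment. There were 4 libraries, 2 from cells with an empty doxycycline-inducible vector and 2 from cells with a c-FOS vector, grouped by the genotype and title in the labels. Per the labels' protocols, total RNA was isolated from adherent cells with a column kit and made into libraries with the Illumina TruSeq RNA kit. Per the series design text, the libraries were sequenced on an Illumina HiSeq instrument, and reads that passed quality filters were aligned with TopHat and then analysed with HOMER. Per the submitters' processing notes, the genome build was mm9, and DESeq2 was also among the tools. Versions, the strand setting of the counting and the gene annotation are not given in the sources used here.

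The deposited table holds 1 value per gene symbol and library. The values the authors deposited are unnormalized expected counts: each is a multiple of 0.5, 48.0% of the values above 0 are not whole, and the columns sum to different totals. How steps of 0.5 arose is not given in the sources used here. The authors' table also gives a gene model length in bases per row, which was used in 1 check of the closing section. The table had 24909 rows, of which 7443 were 0 in all 4 libraries and none lacked a gene name. Of these rows, 26 carried a symbol that reads as a date, as spreadsheet programs write some gene names, and these were not named. In 2 cases a symbol stood on 2 rows, and the row with the highest total count was used, which left 24907 genes. Of these, 24676 symbols were found in the reference gene tables. The build of those tables is not mm9, so no coordinates are given. Flg was the 1 list member with no row.

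The deposited counts were rounded to whole numbers before testing. The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by group (minimum count 10, minimum total 15) and the quasi-likelihood test of c-FOS against control without covariates, two-sided, with Benjamini-Hochberg adjustment at 0.05. This left 12791 genes. Counts-per-million (CPM) values use the effective (TMM) library size. Errors of CPM are SD over n = 2, and errors of log2 fold changes are SE derived from the quasi-likelihood F statistic. With 2 residual degrees of freedom, the gene-wise spread was moderated across genes (prior degrees of freedom 11.3), and the common biological coefficient of variation was 3.38%. A fold against a group at 0 counts is given as a lower bound over a floor of 3 counts in the group, and a fold against 1 to 3 rounded counts as a ratio with an exact 95% counting interval.

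The total counts were 28405433, 29822437.5, 29200592 and 32465409 in control replicates 1 and 2 and c-FOS replicates 1 and 2. The 10 most abundant genes took 9.48%, 9.19%, 10.6% and 10.4% of them, and the ribosomal RNA precursor Rn45s took 4.41%, 4.10%, 4.65% and 4.58%. The TMM factors were 1.05, 1.05, 0.953 and 0.954. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 5 in the control and 1.98 in the c-FOS group, so no pair was treated as repeat deposits of 1 library. This does not show that they came from separate cultures. Counts were simulated for the 12791 genes with the means and library sizes of this comparison. In them, 200 genes with a mean above 1 CPM were changed, 50 at each fold. The quasi-likelihood test of edgeR recovered 62% of changes of 1.25-fold, 90% of 1.5-fold, 98% of 2-fold and 100% of 4-fold. It made 5 false calls, 2.8% of its calls. Far more genes, 8589, passed in the data than were changed in the simulation. The adjusted threshold depends on that share, so these percentages do not carry over to the comparison itself.

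Before the data were examined, 30 gene lists with 669 members were fixed, and 668 members had a row: AP-1 subunits and partners, Hedgehog pathway targets, Hedgehog signal transduction, primary cilium, basal keratinocyte, hair follicle and BCC progenitor, squamous terminal differentiation, wound and hyperproliferation keratinocyte, invasion and matrix proteases, epithelial adhesion, mesenchymal transition, MAPK feedback and ligands, inflammatory cytokines, interferon-stimulated, cell cycle, p53 targets, integrated and unfolded protein stress, heat shock, sterol synthesis, hypoxia and glycolysis, NRF2 targets, TGF-beta and SRF/YAP targets, Wnt feedback genes and ligands, Notch pathway, fibrillar and basement membrane matrix, fibroblast, macrophage and leukocyte, endothelial and melanocyte markers, and replication-dependent histones. Some genes stand on more than 1 list. The 27 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move one way on balance, without comparing them with other genes. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom, so it has little power here.

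The genes named were also fixed by a rule. It took Fos, Gli1, Ptch1, Krt5, Krt14, Krt6a, Krt10, Ivl, Fosl1, Mmp13 and Vim whatever their values. It added the 10 genes with the highest and the 10 with the lowest log2 fold change past the threshold, with an average log2 CPM of at least 2 and both c-FOS libraries on the same side of both control libraries, leaving out predicted genes, clone names, microRNAs, small nucleolar RNAs and ribosomal protein pseudogenes. From each list it took up to 4 members past the threshold with the smallest p, or, where none passed, the 2 with the highest mean CPM. Of the genes the rule takes, 2 are not reported here.

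Alternatives fixed in advance were RLE factors, library totals and upper-quartile factors in place of TMM, Fos left out of the table, no filter on low counts, a filter of at least 50 counts in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, the replicate number as a block, each library left out in turn, and every row as deposited. For the lists they were library totals, RLE factors, a prior count of 0.5, the stricter filter, the estimated correlation, fry, the block and each library left out. Leaving out Rn45s and running camera on ranks were added after the data were seen. No sample column of the table was left out.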

Results

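RNA-seq libraries were made from ASZ001, a cell line derived from a mouse basal cell carcinoma (BCC). The cells carried a doxycycline-inducible vector that was either empty (control) or encoded the transcription factor c-FOS, and both kinds of cell received doxycycline. Each group had 2 libraries. The deposited counts summed to 28405433 and 29822437.5 in the control libraries and to 29200592 and 32465409 in the c-FOS libraries. The series title places the experiment in a study of the transition from basal to squamous cell carcinoma. The comparison asks which transcripts differ between BCC cells with the c-FOS vector and with the empty vector. No library came from c-FOS vector cells without doxycycline. The induction of c-FOS therefore cannot be told apart from other differences between the kinds of cell. The labels number the libraries of a group but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

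Fos, the gene carried by the vector, had counts-per-million (CPM) values of 0.404 and 0.351 in the control libraries and of 296.8 and 313.4 in the c-FOS libraries. The group means were 0.377 ± 0.0369 CPM (SD, n = 2) and 305.1 ± 11.8 CPM (SD, n = 2), a log2 fold change of 9.65 ± 0.09 (SE), with an adjusted p of 4.98e-17 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fos was thus high in both libraries labelled c-FOS and low in both control libraries. The counts do not separate vector-derived from endogenous Fos transcripts. If the vector lacks the mouse untranslated regions or carries the cDNA of another species, the reads were counted in part.

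With c-FOS, the lists of mesenchymal, invasion and protease, MAPK feedback and fibroblast marker transcripts were higher, and those of cell cycle, basal keratinocyte and interferon-stimulated transcripts were lower, in camera at a preset correlation. None of these 7 calls held with an estimated correlation, where the smallest was adjusted p = 0.482. That setting rests on 2 residual degrees of freedom and has little power. The interferon call also did not hold in fry (adjusted p = 0.119). The median log2 fold change of that list was -0.92, and -0.38 without control replicate 1. The fibroblast call was lost in camera with the stricter filter of 50 counts (adjusted p = 0.0622). Vim, which encodes the mesenchymal intermediate filament vimentin, rose from 0.653 ± 0.115 to 432 ± 4.36 CPM (SD, n = 2 per group). Gli1, the transcription factor and target of Hedgehog signalling, fell from 15.1 ± 0.0403 to 2.19 ± 0.214 CPM. Krt5, a keratin of the basal epidermal layer, fell from 11380 ± 399 to 3762 ± 41.3 CPM. Of 12791 genes tested, 8589 (67.1%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 4324 were higher and 4265 lower in the c-FOS libraries, so 50.3% of the changed genes were higher. The median absolute log2 fold change of the changed genes was 0.48, and 989 genes rose and 986 fell by 2-fold or more. The groups did not overlap for 10695 genes (83.6%), where chance gives 33.3% with 2 against 2 libraries.

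The balance of higher and lower calls depended on the scaling between libraries. With library totals in place of TMM factors, 3217 genes were higher and 5879 lower (35.4% of the changed genes higher), and the median log2 fold change over the tested genes was -0.14, against -0.01 with TMM. The medians of 30 lists kept their sign under RLE factors, library totals and upper-quartile factors, except those of heat shock genes (0.10, and -0.04 with library totals) and of NRF2 targets (0.13, and -0.01 with library totals).

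**Figure D1:**
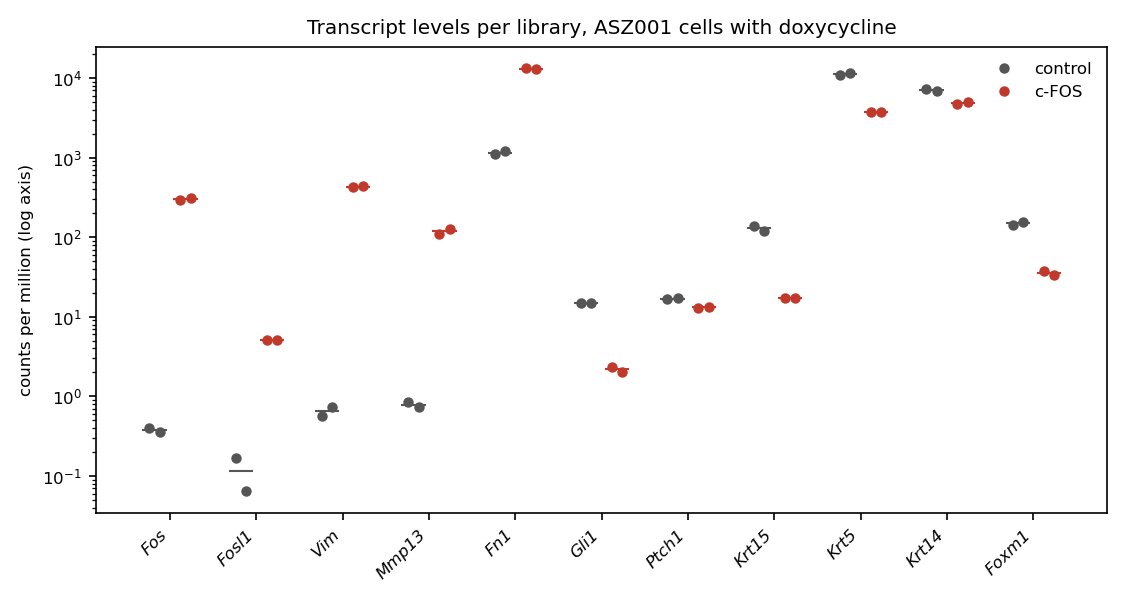
Transcript levels of 11 named genes in each library, in CPM on a log axis. Each point is 1 library (grey, control, n = 2; red, c-FOS, n = 2) and each horizontal line is the group mean; Fos stood at 0.377 and 305.1 CPM, Vim at 0.653 and 432 CPM, and Gli1 at 15.1 and 2.19 CPM in control and c-FOS cells.

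The 10 genes with the highest fold changes included Fos and Vim. Col6a3, which encodes a chain of collagen VI, had 0 counts in both control libraries and 41.4 ± 2.94 CPM (SD, n = 2) with c-FOS, at least 846-fold higher against a floor of 3 counts over the control group. Nlrp2, which encodes an inflammasome-family protein, rose by a log2 fold change of 9.51 ± 0.11 (SE), from 0.147 to 110.7 CPM. Siglecg, a sialic acid-binding lectin, rose by 8.53 ± 0.19 and Angpt4, an angiopoietin, by 8.29 ± 0.19 on the log2 scale. Col5a3, a chain of collagen V, rose by 8.91 on the log2 scale, but by 10.98 without control replicate 1 and 8.06 without control replicate 2. Uchl1, a neuronal ubiquitin hydrolase, rose by 8.56, and by 9.44 without control replicate 2. Prl2c2, a proliferin, had 1 rounded count in the control group, and its ratio was 551 with a 95% counting interval of 98.5 to 21800; its reads may be shared with near-identical proliferin copies. Bmp8a, a bone morphogenetic protein, had 2 control counts and a ratio of 294 with an interval of 81.1 to 2440. Each of these 2 genes was at 0 in 1 control library, so leaving out a control library moved the fitted log2 fold change between 7.97 and 11.06 for Prl2c2 (without control replicate 1 and without control replicate 2) and between 11.18 and 7.08 for Bmp8a in that order. These intervals and floors cover counting error only.

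The genes with the lowest fold changes included Ckmt1, the mitochondrial creatine kinase, which fell by 3.84 ± 0.13 (SE) on the log2 scale, from 35.8 ± 5.03 to 2.48 ± 0.0442 CPM (SD, n = 2 per group). The potassium channel gene Kcnh1 fell by 3.73 and the carnitine synthesis gene Bbox1 fell by 3.47. Id2, an inhibitor of basic helix-loop-helix factors, fell by 3.22, from 37.7 ± 0.798 to 4.05 ± 0.476 CPM. Srcin1 fell by 3.22, Pi15 by 3.15, the receptor phosphatase gene Ptprz1 fell by 3.04 and the DNA helicase gene Pif1 by 2.85. Gas1, a co-receptor for Hedgehog ligands, fell by 2.99 (273.2 ± 16.4 to 34.5 ± 2.42 CPM), and Krt15, a keratin of basal and bulge keratinocytes, fell by 2.91 (128.9 ± 12.9 to 17.2 ± 0.0184 CPM). The adjusted p of these 10 genes lay between 2.27e-14 and 3.7e-10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

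Among the AP-1 subunits and partners other than Fos, which pair with or replace it in the AP-1 dimer, 7 of 11 tested genes rose, 3 fell and 1 did not pass, with the same counts adjusted over the list alone. Fosl2 rose from 629.1 ± 5.65 to 1387 ± 35.4 CPM (SD, n = 2 per group) and Mafk by 0.78 on the log2 scale. Fosl1 rose from 0.116 ± 0.0737 to 5.12 ± 0.0688 CPM, a log2 fold change of 5.43 ± 0.30 (SE) that was 6.24 without control replicate 1. Jun fell by 0.75 on the log2 scale, from 138.1 ± 6.22 to 82.2 ± 0.856 CPM. As a list the genes did not pass in camera (adjusted p = 0.123).

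Lists of genes fixed before the data were examined were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. It called 7 of 27 lists, 4 higher and 3 lower. None of the 7 calls held with an estimated correlation, where the smallest adjusted p was 0.482. The estimate was below the preset value for the invasion (-0.0253), mesenchymal (-0.0474), fibroblast (-0.162) and MAPK (0.00198) lists. For these the loss is not from a higher correlation, and the 2 residual degrees of freedom leave that setting little power. The estimate was above the preset value for the basal keratinocyte (0.0395), interferon (0.804) and cell cycle (0.749) lists. Unless another count is given, the numbers of members that rose and fell were the same when adjusted over the list alone. Exceptions named within a list outside the fixed naming rule were chosen after their values were seen.

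**Figure D2:**
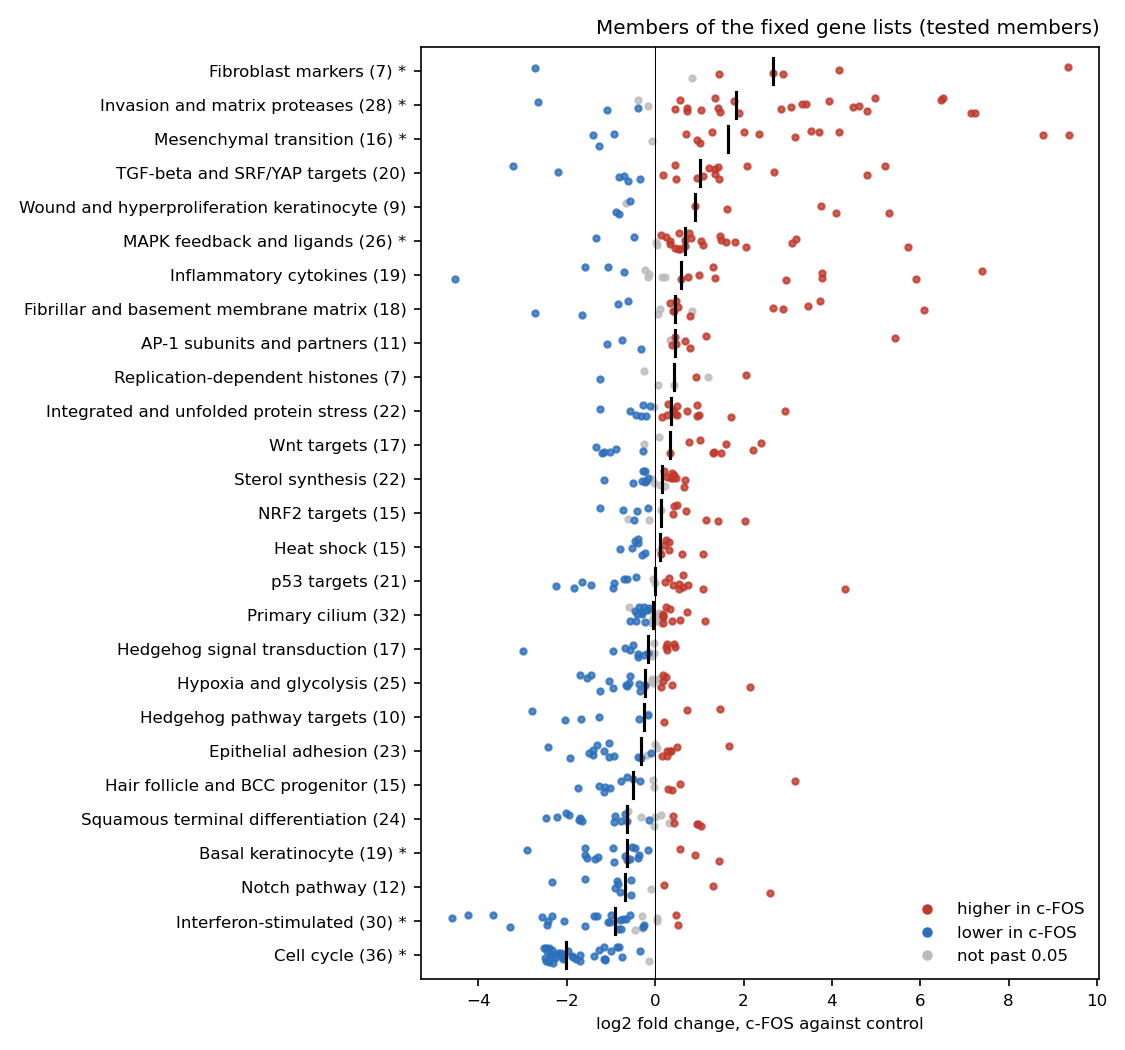
Log2 fold change (c-FOS against control) of the tested members of 27 fixed gene lists, with the number of tested members in parentheses. Each point is 1 gene, coloured by its call at an adjusted p of 0.05 (edgeR quasi-likelihood), black bars are list medians, and an asterisk marks the 7 lists called by camera with the preset correlation; the cell cycle list had a median of -2.02 and the invasion list of 1.84.

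Mesenchymal transcripts rose as a list. Of 16 tested genes of the mesenchymal transition list, 12 rose, 3 fell and 1 did not pass, with a median log2 fold change of 1.65. Besides Vim, Fn1, which encodes the matrix protein fibronectin, rose from 1152 ± 71.6 to 13180 ± 258 CPM, S100a4 rose from 6.59 ± 1.19 to 116.7 ± 0.431 CPM, and Zeb1, a repressor of epithelial genes, rose from 8.41 ± 0.342 to 75.7 ± 0.00509 CPM (SD, n = 2 per group). Snai1, another such repressor, had 0 control counts and was at least 37-fold higher over a floor of 3 counts, and the list median was the same with Snai1 at that bound. The 3 genes that fell were Snai2 (-0.94), a repressor of the same family that basal keratinocytes also express, the cadherin gene Cdh11 (-1.41) and Foxc2 (-1.27). The list's adjusted p in camera was 0.00288, and it was adjusted p = 0.482 with an estimated correlation.

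Invasion and matrix protease transcripts were also higher. Of 28 tested genes, 23 rose, 3 fell and 2 did not pass, with a median log2 fold change of 1.84. The metalloprotease genes Mmp13 (0.788 ± 0.0751 to 119 ± 10.7 CPM), Mmp10 (1.28 ± 0.000288 to 181.1 ± 6.73 CPM) and Mmp12 (3.77 ± 0.534 to 336.9 ± 13.4 CPM; SD, n = 2 per group) rose. The adjusted p in camera was 3.86e-06, and adjusted p = 0.482 with an estimated correlation.

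In the fibrillar and basement membrane matrix list, 11 of 18 tested genes rose and 4 fell (median 0.46 on the log2 scale), and camera did not call it (adjusted p = 0.0668). Col5a1 rose by 6.09, Col6a1 by 3.74 and Col6a2 by 3.46 on the log2 scale, the last by 4.07 without control replicate 1, while the laminin gene Lama5 fell by 0.61. In the list of TGF-beta and SRF/YAP targets, 14 of 20 tested genes rose and 6 fell (median 1.01; camera adjusted p = 0.0562). Ctgf rose by 2.70, Thbs1 by 2.08 and Vcl, which encodes the focal adhesion protein vinculin, by 1.37 on the log2 scale. Both lists crossed the threshold with library totals (adjusted p = 0.0162 for matrix and 0.0062 for TGF-beta and SRF/YAP targets), and the second also with the replicate number as a block (adjusted p = 0.049) and in camera on ranks (adjusted p = 0.0455). Over the alternatives run, the adjusted p lay between 0.0018 and 0.482 for matrix and between 0.00167 and 0.482 for TGF-beta and SRF/YAP targets, where the lowest values are from fry, which tests against no change and not against other genes.

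Markers of fibroblasts moved with these groups. Of 7 tested fibroblast markers, 5 rose, 1 fell and 1 did not pass (median 2.67; camera adjusted p = 0.0357, and adjusted p = 0.482 with an estimated correlation). The call was lost without control replicate 1 (adjusted p = 0.107), without c-FOS replicate 1 (0.0861) and without c-FOS replicate 2 (0.0926), and with the stricter filter of 50 counts (0.0622), within a range of 0.000119 (in fry) to 0.482 over the alternatives run. S100a4 belongs to this list too, Pdgfra rose from 4.24 ± 0.00736 to 11.6 ± 0.369 CPM (SD, n = 2 per group), and Pdgfrb had 0 control counts and was at least 54.7-fold higher over a floor of 3 counts, which left the median as it was. Fbln1 fell by 2.72 on the log2 scale and Col1a1 did not pass (0.83). The summed level of Col1a1, Col1a2, Col3a1, Dcn, Lum and Thy1 in the c-FOS libraries was 3.59 and 4.65 CPM.

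Of the other cell types that a tumour-derived culture could hold, 3 of 12 macrophage and leukocyte markers were expressed highly enough to be tested, and the 3 rose: Csf1r, the receptor for macrophage colony-stimulating factor, from 0.314 ± 0.127 to 18.4 ± 0.0445 CPM (SD, n = 2 per group), Cd14 by 0.68 and Cd68 by 0.38 on the log2 scale. Cd68 did not pass without c-FOS replicate 2 (0.29, adjusted p = 0.0617 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against a lowest value of 4.17e-05 over the alternatives run). Of 4 tested endothelial markers, Flt1 (1.85), Tek (1.35) and Pecam1 (0.31) rose and Egfl7 fell by 0.66 on the log2 scale. The 2 tested melanocyte markers did not pass, with log2 fold changes of -0.01 for Mitf and -0.72 for Pmel, but both passed as lower with library totals (-0.15 and -0.86; adjusted p = 0.0217 and 0.04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and up to 0.969 and 0.439 over the alternatives run). These 3 lists had too few tested members for a list test.

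Basal keratinocyte transcripts fell as a list. Of 19 tested genes, 16 fell and 3 rose, with a median log2 fold change of -0.64. Krt15 fell as given above, and Krt5 fell by 1.60 ± 0.04 (SE), Trp63, which encodes the p63 factor of stratified epithelia, by 1.54 ± 0.04 and the hemidesmosome gene Dst by 1.36 ± 0.04 on the log2 scale. Krt14, the partner of Krt5, fell by 0.53 ± 0.04 (7137 ± 222 to 4944 ± 206 CPM; SD, n = 2 per group). The 3 that rose were the integrin genes Itgb1 (1.44) and Itga6 (0.57) and the laminin gene Lamb3 (0.91). The camera adjusted p was 0.000718, and adjusted p = 0.482 with an estimated correlation.

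Epithelial adhesion genes went both ways: 13 of 23 tested fell, 7 rose and 3 did not pass (median -0.31; camera adjusted p = 0.0682, or 0.0455 on ranks). Cdh1, which encodes E-cadherin, fell from 349.5 ± 9.86 to 131 ± 0.753 CPM (SD, n = 2 per group), and Grhl2 fell by 1.51, the desmosomal cadherin gene Dsc3 by 1.15 and the splicing regulator gene Esrp1 by 1.05 on the log2 scale. Among 15 tested hair follicle and BCC progenitor genes, 9 fell, 4 rose and 2 did not pass (median -0.50; camera adjusted p = 0.143). Krt17 fell from 5238 ± 161 to 2574 ± 134 CPM, Tcf7l1 fell by 1.28 and Vdr by 0.76 on the log2 scale, whereas the stem cell receptor gene Lgr6 rose from 7.42 ± 0.0768 to 66.4 ± 3.36 CPM.

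Transcripts of squamous terminal differentiation were mostly low in both groups, and 24 of 48 listed genes were tested. Of these, 13 fell, 5 rose and 6 did not pass (median -0.63; camera adjusted p = 0.123). Spink5, a protease inhibitor of the cornifying epidermis, fell by 1.66, Ovol1 by 1.71 and Sbsn by 0.94 on the log2 scale, while Evpl, which encodes envoplakin, rose by 0.97 (121.6 ± 3.88 to 237.3 ± 5.01 CPM; SD, n = 2 per group). The early differentiation keratin Krt10 was at 4.09 ± 0.129 CPM in control and 3.3 ± 0.00984 CPM in c-FOS cells and did not pass (-0.31, adjusted p = 0.0685 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed with library totals (-0.45) and with upper-quartile factors (-0.37). Ivl, which encodes the envelope protein involucrin, fell from 0.458 to 0.138 CPM (-1.72, adjusted p = 0.00773 in the same test), but did not pass in DESeq2 (adjusted p = 0.142) or without c-FOS replicate 2 (-1.33, adjusted p = 0.132). Over all alternatives run, the adjusted p of Ivl lay between 0.00228 and 0.142.

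In the list of wound and hyperproliferation keratinocyte genes, 5 of 9 tested rose, 3 fell and 1 did not pass, and 4 fell when adjusted over the list alone (median 0.90; camera adjusted p = 0.389). The genes that rose included the S100 genes S100a7a (0.461 ± 0.109 to 18.1 ± 0.915 CPM), S100a6 (487.3 ± 6.54 to 1511 ± 45.6 CPM; SD, n = 2 per group) and S100a10 (0.90 on the log2 scale). The 3 that fell were keratins of wounded epidermis, namely Krt6a (-0.56), Krt6b (-0.89) and Krt16 (-0.82); Krt6a and Krt6b are close in sequence and can share reads.

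Hedgehog signalling drives BCC. Of 10 tested Hedgehog pathway targets, 6 fell, 3 rose and 1 did not pass (median -0.26; camera adjusted p = 0.143). Gli1 fell by 2.79 ± 0.12 (SE), Foxl1 by 2.05 ± 0.14 and Sfrp1 by 1.68 ± 0.04 on the log2 scale. Ptch1, the Hedgehog receptor and target gene, fell by 0.36 ± 0.08, from 16.9 ± 0.241 to 13.1 ± 0.111 CPM (SD, n = 2 per group). Ccnd1, which encodes cyclin D1 and answers to many pathways, rose by 1.47 ± 0.04. In the Hedgehog signal transduction list, 9 of 17 tested fell, 5 rose and 3 did not pass (median -0.17; camera adjusted p = 0.203), with Gas1 as given above, Gli2 falling by 0.97, the co-receptor gene Boc by 0.67 and Sufu by 0.57 on the log2 scale. Genes of the primary cilium, the organelle of Hedgehog signalling, were evenly divided, with 10 of 32 higher, 11 lower and 11 not past (median -0.04; camera adjusted p = 0.738). The cilium genes with the smallest p were Tctn2 (1.12), Kif3b (0.39), Ift81 (-0.44) and Ift80 (-0.40).

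MAPK feedback and ligand transcripts rose as a list, with 22 of 26 tested higher, 2 lower and 2 not past (median 0.67). Dusp4, a phosphatase that acts on ERK, rose from 0.753 ± 0.0189 to 40.2 ± 1.93 CPM, the EGF receptor ligand gene Hbegf from 5.25 ± 0.712 to 21.9 ± 0.237 CPM, and Epha2 from 45.4 ± 4.23 to 125.6 ± 1.10 CPM (SD, n = 2 per group). Epha4 fell by 1.34 on the log2 scale. The camera adjusted p was 9.81e-05, and adjusted p = 0.482 with an estimated correlation. Of 19 tested inflammatory cytokine genes, 10 rose, 4 fell and 5 did not pass (median 0.58; camera adjusted p = 0.143). Ptgs2, the inducible cyclooxygenase gene, rose from 39.4 ± 2.71 to 309.5 ± 7.73 CPM and the chemokine gene Ccl2 by 5.91 on the log2 scale. Ccl7 had 2 control counts and a ratio of 190 with a 95% counting interval of 52.2 to 1580, and Cxcl14 fell by 1.59 on the log2 scale. The cytokine and the AP-1 lists crossed the threshold with library totals (adjusted p = 0.0478 and 0.0472), within ranges of 0.00149 to 0.511 and 0.00722 to 0.554 over the alternatives run, the lowest values from fry.

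Cell cycle transcripts fell almost throughout. Of 36 tested S phase and mitosis genes, 35 fell and 1 did not pass, with a median log2 fold change of -2.02. Foxm1, a transcription factor of mitotic genes, fell from 150.1 ± 8.35 to 35.5 ± 3.20 CPM, Cdc20 from 77.9 ± 1.43 to 15.2 ± 0.598 CPM, the kinase gene Plk1 from 74.6 ± 1.31 to 14.8 ± 1.44 CPM and the motor gene Kif11 from 127.1 ± 8.73 to 24.2 ± 2.70 CPM (SD, n = 2 per group). The camera adjusted p was 3.85e-11, and adjusted p = 0.554 with an estimated correlation. Among 21 tested p53 targets, 10 rose, 9 fell and 2 did not pass (median -0.01; camera adjusted p = 0.895). Camera gave this list the upward direction, against its median and its mean of -0.07. Btg2 fell by 2.25, Gtse1 by 1.83, Trp53inp1 by 1.44 and Perp by 0.93 on the log2 scale. Of 7 tested replication-dependent histone genes, Hist1h2bc (2.06) and Hist1h1c (0.93) rose, Hist1h1e fell and 4 did not pass (median 0.42, camera adjusted p = 0.603). The wider set of 25 tested genes whose symbols start with Hist went the other way, with 5 higher and 11 lower (median -0.94). That set comes from the later scan of gene families, where its camera adjusted p was 0.356. Near-identical histone copies can share reads.

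Interferon-stimulated transcripts were lower as a list, with 23 of 30 tested lower, 2 higher and 5 not past (median -0.92). Tap1, the peptide transporter of antigen presentation, fell from 14 ± 2.85 to 2.78 ± 0.319 CPM and Ifit2 from 26.9 ± 2.62 to 13.2 ± 0.664 CPM (SD, n = 2 per group). Rsad2, an antiviral enzyme gene, fell by 3.29 on the log2 scale, or by 2.67 without control replicate 1. The 2 that rose were B2m (0.51) and Xaf1 (0.47). The control libraries differed: 30 of 30 members were higher in control replicate 1 than in control replicate 2, by a median of 0.60 on the log2 scale. Without control replicate 1 the list median was -0.38, and without control replicate 2 it was -1.26. The camera adjusted p was 0.0055, and adjusted p = 0.69 with an estimated correlation, while fry gave 0.119; over the alternatives run it lay between 1.75e-06 and 0.69.

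**Figure D3:**
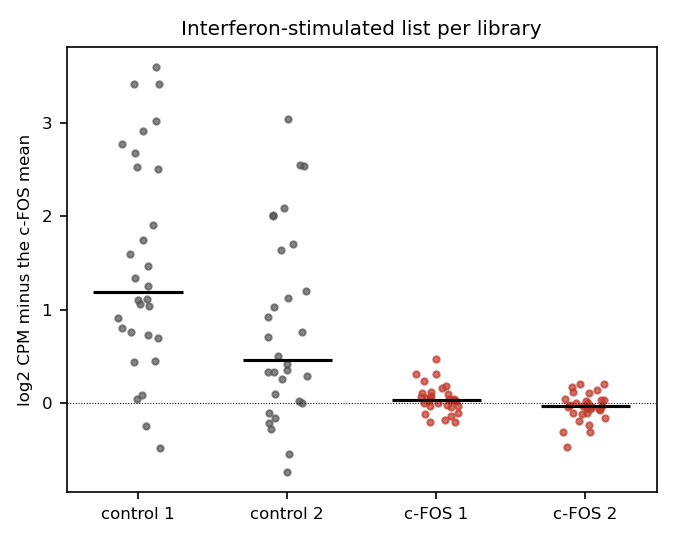
Level of the 30 tested interferon-stimulated genes in each library, as log2 CPM minus the mean of the c-FOS libraries. Each point is 1 gene and each black bar is the library's median, which was 1.19 and 0.47 in control replicates 1 and 2 and 0.04 and -0.04 in c-FOS replicates 1 and 2.

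Other pathway lists moved in both directions and were not called by camera at the preset correlation, though camera on ranks, chosen after the data were seen, called the hypoxia and Notch lists (adjusted p = 0.0459 and 0.0455). Of 22 tested genes of the integrated and unfolded protein stress responses, 14 rose, 7 fell and 1 did not pass (median 0.35; adjusted p = 0.123). Those with the smallest p were Nupr1 (34.6 ± 0.986 to 266.7 ± 7.56 CPM; SD, n = 2 per group), Chac1 (1.72), Xbp1 (1.00) and the chaperone gene Hspa5 (0.71 on the log2 scale). Hypoxia and glycolysis genes were lower in 13 and higher in 6 of 25, or lower in 14 when adjusted over the list alone (median -0.23; adjusted p = 0.0731). The glucose transporter gene Slc2a1 fell by 1.46, Ddit4 by 1.55 and Pfkl by 1.04, while Ndrg1 rose by 2.14 on the log2 scale. In the Notch list, 8 of 12 fell, 3 rose and 1 did not pass (median -0.67; adjusted p = 0.0731). The ligand gene Jag1 rose from 139.2 ± 7.45 to 846.1 ± 28.3 CPM, whereas Dll1 fell by 1.59, Jag2 by 0.91 and Notch1 by 0.79 on the log2 scale. In the Wnt list, which holds feedback genes and ligands, 9 of 17 rose and 6 fell (median 0.34; adjusted p = 0.5). The 4 with the smallest p encode ligands and not pathway targets, with Wnt7a (2.40) and Wnt7b (1.31) higher and Wnt4 (-1.35) and Wnt10a (-1.02) lower.

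Of 15 tested NRF2 targets, 7 rose, 5 fell and 3 did not pass (median 0.13; camera adjusted p = 0.603). Akr1b8 rose by 2.04, Srxn1 by 1.42 and Txnrd1 by 0.69 on the log2 scale, and the cystine transporter gene Slc7a11 fell by 1.24. Sterol synthesis genes rose in 10 and fell in 8 of 22 (median 0.16, camera adjusted p = 0.569). Among those with the smallest p, Hsd17b7 rose by 0.68, Sc5d by 0.64 and Sqle by 0.36 on the log2 scale. Heat shock genes were divided, with 7 of 15 higher, 7 lower and 1 not past (camera adjusted p = 0.751). Their median was 0.10, their mean -0.01 and the direction in camera downward. Cryab rose by 1.09 and Bag3 by 0.61, while Dnajb1 fell by 0.79 and Hspb1 by 0.40 on the log2 scale.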

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

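Leaving out Rn45s and running camera on ranks were tests chosen after the data were seen. Counts of changed genes stayed within 1.5 times of the 8589 in every alternative run, from 7096 with DESeq2 (7036 of them shared in direction) to 9096 with library totals (7482 shared), and the genes changed 2-fold or more numbered 973 higher and 884 lower in DESeq2. With 1 library left out, where the lone sample of a group is assumed to vary like the other group, the ranges were 7179 to 8878 changed, 3698 to 4520 higher, 3481 to 4358 lower, 961 to 1077 higher and 937 to 1051 lower by 2-fold or more, and 9.55 to 9.75 for the log2 fold change of Fos. The called lists numbered 7 at the preset correlation, 11 with library totals, 0 with an estimated correlation, 21 with fry and 11 with camera on ranks. The estimated correlation has little power with 2 residual degrees of freedom. Fry tests against no change and not against other genes, of which 67.1% changed, so its number of lists answers another question. The cause of the differences with library totals and with ranks was not tested. The interferon list passed without control replicate 1 (0.00951). With the replicate block, 8464 genes changed (8397 shared), 4246 higher and 4218 lower, and 8 lists were called; the labels give no shared culture or day, and same-numbered libraries did not deviate together (Pearson -0.07, Spearman -0.14 across genes, 2 pairs), so the pairing was not used. Of 136 named genes, 1 lost its call in DESeq2 and 2 without c-FOS replicate 2, while 3 gained one with library totals and 1 with upper-quartile factors. Mitf, not past the threshold, changed sign to 0.023 without control replicate 2 and 0.033 without c-FOS replicate 1 (range -0.051 to 0.033). The p53 list changed direction in fry (adjusted p = 0.0322), with the replicate block (0.983) and without control replicate 2 (0.936; range with 1 library left out 0.79 to 0.993), and the histone list without c-FOS replicate 2 (0.926; range 0.635 to 0.926); the cause was not tested. At this depth the smallest simulated changes were recovered in 62% of genes, so small changes can be missed.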

Other observations

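The gene families, the single genes outside the fixed rule and the tests below were chosen after results were seen, except the test on other transcripts with a 5' terminal oligopyrimidine tract, which was fixed before its result was seen. Symbols were grouped into 208 families by their first letters, and camera at the preset correlation called 8. None of these held with an estimated correlation (adjusted p = 0.893 for each), a setting with little power here. Annexin genes, which encode calcium-dependent membrane-binding proteins, were higher in 9 of 10 (median log2 fold change 0.86; camera adjusted p = 0.00223), led by Anxa5, which rose from 170.8 ± 4.17 to 589.6 ± 7.54 CPM (SD, n = 2 per group), Anxa8 (1.53) and Anxa6 (1.47). Rab genes of vesicle transport were higher in 36 and lower in 7 of 58 (median 0.25; adjusted p = 0.00394). Keratin genes were lower in 14 of 17 and higher in 1, Krt42 (2.44), with an adjusted p of 0.00367. The 8 Ugt1a symbols fell alike (median -1.39), but they are annotated on shared exons and 4 had identical values, so they stand for about 1 measurement. Snhg genes, host transcripts of small nucleolar RNAs, were lower in 11 of 14 (median -0.54; adjusted p = 0.0454), and Mcm genes of the replication helicase in 9 of 10 (adjusted p = 0.0444).

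Of 10 tested genes whose symbols start with Cdkn, most of them inhibitors of cyclin-dependent kinases, 3 were higher and 7 lower (median -0.61; camera adjusted p = 0.406). Cdkn2b rose from 56.8 ± 4.39 to 260.2 ± 4.57 CPM and Cdkn2a from 94.2 ± 1.19 to 229.5 ± 3.47 CPM (SD, n = 2 per group), whereas Cdkn1a, a p53 target, fell by 0.64 on the log2 scale. Inhba, which encodes a subunit of activin, rose from 184.6 ± 13.1 to 1877 ± 39.9 CPM and the integrin gene Itgb3 from 6.66 ± 0.428 to 55.4 ± 2.77 CPM. The Id genes, targets of BMP signalling, fell together, with log2 fold changes of -2.19 for Id1, -3.22 for Id2 and -0.61 for Id3, and with Id4 at 14.5 ± 0.0651 against 3.62 ± 0.0586 CPM, while Bmp4 rose by 1.60 and Bmp7 fell by 1.38. Egfr fell by 1.55. These genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with both c-FOS libraries on the same side of both controls.

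The mesenchymal transcripts that rose with c-FOS could come from other cells in the cultures. The summed level of Col1a1, Col1a2, Col3a1, Dcn, Lum and Thy1 reached at most 1.07% of the Vim level in a c-FOS library. At least 10% was set as the mark of fibroblasts, so the sum argues only against fibroblasts rich in these 6 transcripts. Of the 7 tested fibroblast markers 5 rose and 1 fell, and S100a4 stood at 116.7 and Pdgfra at 11.6 CPM with c-FOS. Other collagen genes were abundant with c-FOS, with Col6a1 at 340.9 and Col5a1 at 131.5 CPM. Leukocytes would bring Ptprc, Lyz2 and the like with Csf1r, but the summed level of 9 leukocyte genes was at most 3.32% of that of Csf1r. These 9 were the listed markers too low to be tested, so a low sum was in part fixed in advance. Of the tested markers left out of the sum, Cd14 rose from 6.47 to 10.3 CPM and Cd68 from 11.09 to 14.35 CPM. A lower share of keratinocyte cells as the whole cause was set to lower the 42 tested basal keratinocyte and epithelial adhesion genes alike. Of them, 10 rose and 29 fell, where 4324 of all 12791 tested genes rose. Other cells may also express some of these genes, so the 10 that rose cannot decide this question. A lower share of keratinocyte cells remains open, and a response of the ASZ001 cells to c-FOS remains open as a hypothesis. So does a selection of cells during the making of the lines, which was not tested.

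The lower interferon list may reflect a response in the control cells, since 30 of 30 members stood higher in control replicate 1 than in control replicate 2. The fit without control replicate 1 cannot decide whether a raised response in that library is the whole cause. It leaves 1 control library, whose own level cannot be told from a group difference. The members also move together, with an estimated correlation of 0.804. In that fit the median was -0.38 in place of -0.92, so that control replicate 1 sets much of the size. A response in control replicate 1 alone, a response in both control libraries to different degrees, and an effect of c-FOS all remain open. With an estimated correlation the list had an adjusted p of 0.69.

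Ribosomal protein genes were lower in 59 and higher in 1 of 79, with a median log2 fold change of -0.51. Their transcripts are short and abundant. Among 10000 random lists matched on gene model length and mean expression none had so low a median (lowest -0.32), which gives a percentile of 0.01, the smallest these lists can give. However, the Rpl and Rps families were taken up because they led the scan of 208 families. The random lists draw each gene singly, without the shared movement of a gene family, and how close the matches lay was not checked. The percentile therefore cannot decide whether length and expression are the whole cause. Scaling as the whole cause is argued against, since a factor per library moves every gene alike and the median of the ribosomal protein genes lay -0.504 from that of all tested genes. A further 17 transcripts with a 5' terminal oligopyrimidine tract, most of them for translation factors, were lower in 15 and higher in 0 (median -0.35). They lay at a percentile of 0.08 of their own matched lists, drawn in the same way. A fall shared by this transcript class is a candidate only. Reads shared between these genes and their pseudogenes remain open, and camera with an estimated correlation gave an unadjusted p of 0.0378 for the ribosomal proteins and 0.0621 for the others, against an adjusted p of 0.893 for the Rpl and Rps symbols in the scan of 208 families. Families in neither set were also mostly lower, though camera at the preset correlation did not call them. Ndufa genes were lower in 10 and higher in 0 of 13 (median -0.28). Cox genes were lower in 15 and higher in 1 of 20 (-0.24), and Srsf genes lower in 7 and higher in 0 of 10 (-0.41). Mrps genes were lower in 9 and higher in 5 of 29 (0.007). A fall particular to transcripts with such a tract is therefore not shown.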
